A study of Homo sapiens with 2 samples.

How the data were processed

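Single-cell RNA sequencing had been run on 2 libraries of organoids differentiated from H1, an established human embryonic stem cell line. Per the labels, both libraries belong to 1 group treated with "FGF2+7" and were collected on day 14 of stage 7, and no untreated library was analysed here. Organoids were dispersed to single cells, about 16000 cells were loaded per channel and about 10000 captured, per the labels' protocols, with version 3 of the 10x Genomics 3' kit.

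The deposited matrices held counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. Alignment and counting with Cell Ranger 4.0.0 on GRCh38 is given in the submitters' processing notes, whereas both matrices name version 6.1.2, per the file headers. The annotation behind the 33538 genes is not given in the sources used here; 33456 of them matched GENCODE release 29 by Ensembl ID, and gene coordinates below are from that release on GRCh38. Replicate 1 held 19158 barcodes and 139934047 UMIs (median 5693 per barcode), and replicate 2 held 10296 barcodes and 130463352 UMIs (median 11785). No barcode in either library had fewer than 500 UMIs. The libraries differed in barcode number and make-up and were counted as 2 replicates. No label says whether they came from separate cultures. The p-values measure how far class differences varied between these libraries, after the overall library difference was removed. That variation may be technical.

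Before the data were examined, the cell filter, clustering settings, marker genes, 12 gene lists, tests and the rule for named genes were fixed. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept (17317 in replicate 1 and 9755 in replicate 2). Scrublet, run per library in scanpy 1.11.5, marked 1515 (8.75%) and 334 (3.42%) of them as doublets, which were removed, leaving 15802 and 9421 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across libraries, and Leiden clustering at resolution 1 was run on 30 principal components and 15 neighbours without integration. To keep tested genes apart from cluster definition, clustering used genes with odd Ensembl ID numbers outside the gene lists, plus the markers; genes with even numbers and the list genes, without the markers, were tested.

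The planned comparisons could not be made as written. Clustering at resolution 1 gave 31 clusters, none of which could be named delta-like, and in replicate 2 the delta-like class formed later (39 cells) and the beta-like class (28 cells) lay below the planned minimum of 50 cells per library. The following choices were therefore made after seeing the data. The 3 clusters with SST, INS, GCG, PPY, GHRL or TPH1 among their 10 genes with the highest fold, and a median depth of at least 0.333 of that of their libraries, were clustered again on their own at the same resolution, giving 12 sub-clusters; other numbers of components, another scaling and resolution 0.5 had been looked at before this set-up was adopted. A class name required at least 3, and at least 50%, of its fixed markers at 20 CPM and at 3 times the level of cells outside the endocrine clusters, more markers than any other class, and at least 1 marker, and no fewer than any other class, among the 10 genes with the highest fold. The minimum was lowered to 20 cells per class and library. Clusters with a median depth below 0.333 of that of their libraries were left unnamed unless a marker led them.

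UMIs were summed per library and class and compared with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, robust quasi-likelihood F-test), with class and library as terms. Because the classes compared are parts of the same libraries, library was a block from the outset. The fit had 8 sums, 3 residual degrees of freedom and 13490 genes, of which 6943 kept out of the clustering were tested; p-values were adjusted by Benjamini-Hochberg over these. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM, scaled by TMM for tested genes and unscaled for markers. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, with an estimated correlation beside it), adjusted over the 12 lists of a comparison, and list members were also adjusted over the list alone. The lists covered islet transcription factors, receptors acting on islet secretion, ion channels, exocytosis machinery, granule proteins and prohormone processing, glucose sensing and fuel metabolism, FGF signalling, gut hormones, neuronal adhesion and synapse genes, endoplasmic reticulum stress, dissociation and heat shock, and hypoxia.

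Genes were named by a fixed rule: among tested genes with adjusted p under 0.05, the same direction in both libraries and at least 50 CPM in the higher class, the 8 largest changes in each direction, leaving out clone names and mitochondrial and ribosomal protein genes; the 2 to 4 members of each list with the lowest p; and FGFR1 to FGFR4. Some genes that the rule selected, or that served as markers, are not reported here by name, and they stay in the list counts. Markers and islet hormones describe identity and are not counted as differences. A cell's leading hormone was the most abundant of SST, INS, GCG, PPY and GHRL if it had at least 10 UMIs. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only, and hormone detection was also computed after thinning every cell to 3000 UMIs, which left out 4835 cells of replicate 1 and 1186 of replicate 2 that were shallower.

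The tests were checked on simulated counts, with known folds given to 200 of the 6943 genes tested. The changed genes had at least 50 CPM, so recovery of changes at lower levels was not checked. Counts were drawn from the means and dispersion of the fitted model, with the classes taken as given. Errors from forming classes by clustering, or from departures from that model, are therefore not covered. In the delta-like against beta-like setting 96.0% of 2-fold and 100% of 4-fold changes were recovered with 4.9% false calls; against alpha-like cells these were 95.0%, 100% and 2.0%, and against enterochromaffin-like cells 94.0%, 100% and 2.5%. Alternatives were DESeq2 1.42.0, median-of-ratios (RLE) size factors, no low-count filter, no replicate block, fits with only the 2 classes, count splitting, a stricter cell filter (1000 genes, 10% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, library-centred genes, all variable genes, other hormone thresholds and each library left out. Added after seeing the data were classes defined by the leading hormone (at least 50 UMIs, within the endocrine clusters) and a minimum of 10 cells where another setting left fewer than 20.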

Results

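Organoids were made from H1 human embryonic stem cells by a protocol directed at pancreatic delta cells, the somatostatin-secreting cells of the islet. The data addressed which endocrine cells such organoids contained and how their delta-like cells differed from the other endocrine classes. All cells came from 1 treatment group with 2 libraries, so every comparison was between cell classes within organoids. After filtering, 15802 cells of replicate 1 and 9421 cells of replicate 2 remained, of 19158 and 10296 barcodes; about 10000 captured cells per channel are stated in the labels.

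Endocrine cells formed 12.6% of replicate 1 (1990 cells, 95% interval 12.1 to 13.1) and 3.46% of replicate 2 (326 cells, 3.10 to 3.85), a mean of 8.03% ± 6.46 (SD, n = 2). Alpha-like cells made up 4.77% and 1.06% (753 and 100 cells). Enterochromaffin-like cells, which resemble the serotonin-producing cells of the gut, were 3.12% and 1.04% (493 and 98 cells), and beta-like cells 2.25% and 0.297% (356 and 28 cells). Which of the alpha-like and enterochromaffin-like classes was larger depended on the processing. Enterochromaffin-like cells were more frequent in both libraries with doublets kept (769 and 104 against 699 and 99 cells), with all variable genes (601 and 109 against 414 and 15) and under count splitting (557 and 106 against 420 and 14). In replicate 2 alone they were more frequent at resolution 0.5 (108 against 99), at resolution 2 (98 against 21) and with library-centred genes (96 against 81). Delta-like cells were 1.11% of replicate 1 (176 cells, interval 0.956 to 1.29) and 0.414% of replicate 2 (39 cells, 0.295 to 0.566), a mean of 0.764% ± 0.495 (SD, n = 2). Within the endocrine cells, delta-like cells took 8.84% of replicate 1 and 11.96% of replicate 2. Different sub-clusters held most alpha-like cells: of 12 sub-clusters, number 0 (led by GCG and PYY) held 340 and 15 cells and number 5 (led by GAST and DPP4) 349 and 79. A further 212 and 61 endocrine cells (1.34% and 0.648%) were left in unnamed sub-clusters. The delta-like class depended on the clustering: no sub-cluster earned the name at resolution 0.5 or with library-centred genes, and the mean share was 0.287% at resolution 2 and 0.370% with all variable genes. Under count splitting it was 0.595% of replicate 1 and 0.244% of replicate 2.

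**Figure D1:**
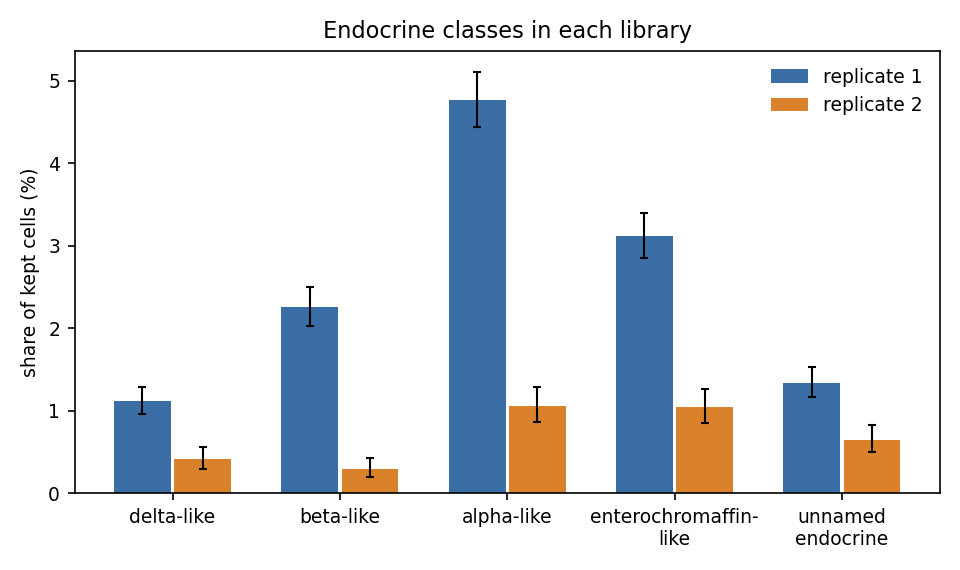
Share of kept cells (%) in each endocrine class for replicate 1 (15802 cells) and replicate 2 (9421 cells); bars start at 0 and error bars are exact 95% binomial intervals, which cover counting error only. Each class took a larger share of replicate 1, from 1.11% against 0.414% in delta-like cells to 4.77% against 1.06% in alpha-like cells.

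The classes carried the markers they were named from. Delta-like cells held SST, the somatostatin gene (chromosome 3, 187668906 to 187670399), at 38925 and 20830 CPM in replicates 1 and 2, together with HHEX, a transcription factor of delta cells (chromosome 10, 92689951 to 92695646), at 39.1 and 47.1 CPM. The 55 and 9 delta-like cells with fewer than 10 SST UMIs held HHEX at 0 CPM in both libraries. Delta-like cells also held LEPR, the leptin receptor, at 135 and 113 CPM, and RBP4 at 36.6 and 59.7 CPM. GHRL, the ghrelin gene (chromosome 3, 10285675 to 10292947), had the highest fold of any gene in this sub-cluster, at 721 and 4381 CPM over all of its cells, of which 14 of 176 and 10 of 39 held at least 10 GHRL UMIs. It stood at 6.98 and 9.05 CPM in alpha-like cells and 8.67 and 5.26 CPM in beta-like cells. Beta-like cells held INS, the insulin gene (chromosome 11, 2159779 to 2161341), at 30366 and 19081 CPM, IAPP at 1022 and 367 CPM and NKX6-1 at 73.7 and 80.2 CPM. At least 10 UMIs of GCG, the glucagon gene (chromosome 2, 162142873 to 162152404), were present in 71.2% and 43.0% of alpha-like cells, at 25307 and 5116 CPM over all of them. Enterochromaffin-like cells held TPH1, the rate-limiting enzyme of serotonin synthesis, at 2575 and 2162 CPM and FEV at 322 and 314 CPM.

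**Figure D2:**
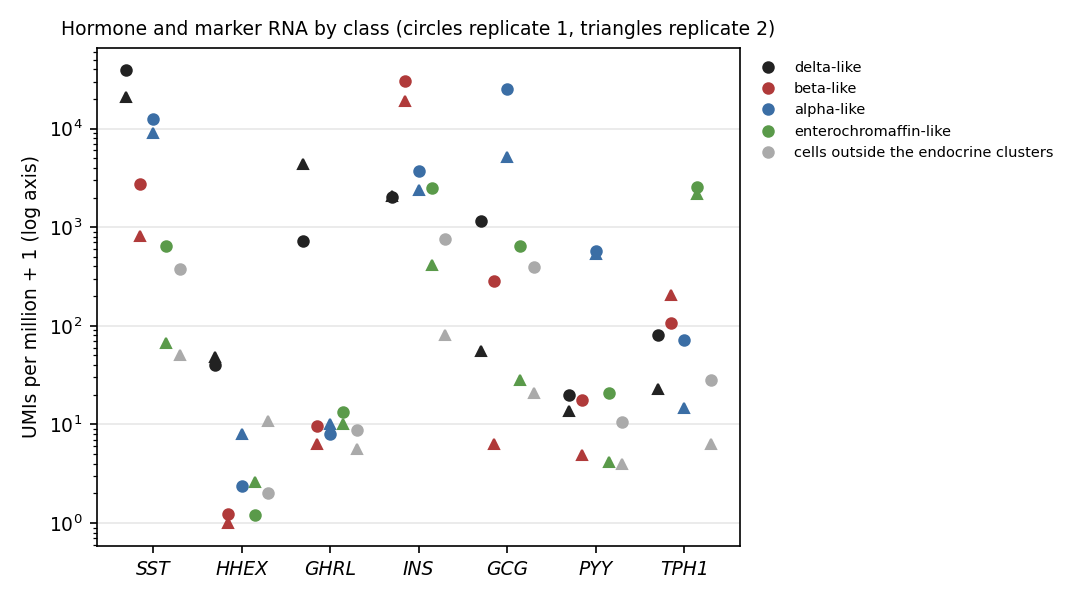
Hormone and marker RNA in CPM plus 1 (log axis) for 7 genes on the horizontal axis, by cell class (colours) and library (circles replicate 1, triangles replicate 2). SST was highest in delta-like cells (38925 and 20830 CPM) and next highest in alpha-like cells (12397 and 9014 CPM).

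SST led the hormones in 403 of 15802 cells of replicate 1 (2.55%, interval 2.31 to 2.81) and 128 of 9421 of replicate 2 (1.36%, 1.13 to 1.61), a mean of 1.95% ± 0.843 (SD, n = 2). INS led in 7.85% and 1.40% of cells and GCG in 4.09% and 0.414%. The 1240 INS-led cells of replicate 1 outnumbered its 356 beta-like cells, so this share does not measure beta-like cells. Outside the endocrine clusters of replicate 1, 773 of 13812 cells (5.60%) held at least 10 INS UMIs. After thinning to 3000 UMIs, 0.922% of the 9112 such cells deep enough did. Whether this INS was free RNA was not tested. Most cells of the delta-like class were SST-led, 116 of 176 (65.9%, 58.4 to 72.9) in replicate 1 and 27 of 39 (69.2%, 52.4 to 83.0) in replicate 2. The alpha-like class held 147 SST-led cells in replicate 1 and 26 in replicate 2, so that SST-led cells were not confined to delta-like cells. These shares depended on the threshold. With a minimum of 5 UMIs, INS led in 32.9% and 1.61% of cells, SST in 5.46% and 1.73% and GCG in 7.95% and 0.446%. With a minimum of 20 UMIs, INS led in 3.60% and 1.16% of cells and SST in 2.06% and 1.09%. With a minimum of 50 UMIs, INS led in 2.70% and 0.786%, SST in 1.73% and 0.679% and GCG in 2.77% and 0.276%.

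SST and GCG RNA were found together in alpha-like cells. In cells thinned to 3000 UMIs, at least 10 SST UMIs were present in 35.4% and 29% of alpha-like cells and 63.5% and 66.7% of delta-like cells. The shares were 2.20% and 1.03% of enterochromaffin-like cells and 0.593% and 0.291% of cells outside the endocrine clusters. At the deposited depth these shares were 47.4% and 41.0% in alpha-like cells, 61.0% and 64.3% in beta-like cells, 68.8% and 76.9% in delta-like cells and 1.51% and 0.836% outside the endocrine clusters. Median depth outside these clusters was 5402 and 11814 UMIs against 11825 and 19497 in alpha-like cells. Both SST and GCG reached 10 UMIs in 26.3% and 13.0% of thinned alpha-like cells, and both INS and GCG in 20.8% and 3.00%. At the deposited depth SST with GCG was seen in 38.1% and 19.0% of alpha-like cells, and INS with GCG in 55.1% and 26.0%. In thinned delta-like cells GCG reached 10 UMIs in 5 of 170 cells of replicate 1, and GHRL in 10 of 170 (5.88%) and 6 of 39 (15.4%). SST with INS was seen in 23.3% of thinned beta-like cells of replicate 1 but in 1 of 28 (3.57%) in replicate 2.

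**Figure D3:**
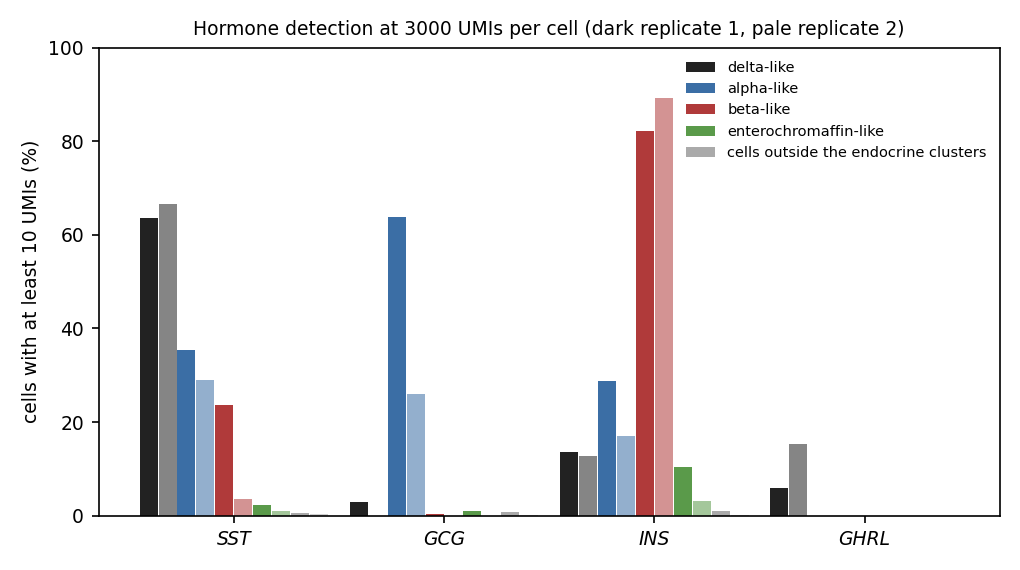
Share of cells (%) with at least 10 UMIs of SST, GCG, INS or GHRL after thinning each cell to 3000 UMIs, by class (colours) and library (dark replicate 1, pale replicate 2). SST passed this level in 63.5% and 66.7% of delta-like and in 35.4% and 29% of alpha-like cells.

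Delta-like and beta-like cells differed in 720 of 6943 tested genes, 357 higher and 363 lower in delta-like cells (edgeR, adjusted p under 0.05). In this and the other comparisons, the delta-like class included its 55 and 9 cells with fewer than 10 SST UMIs. It also included the 14 of 176 and 10 of 39 cells with at least 10 GHRL UMIs. Which of its cells carried a given difference was not tested. The largest rise was in FGF13, an intracellular member of the FGF family that binds sodium channels, at 460 and 568 CPM against 20.4 and 29.8 (log2 fold change 4.38 ± 0.20 SE, adjusted p = 3.74e-08). Near it were SV2C, a synaptic vesicle protein (4.35 ± 0.33, adjusted p = 2.1e-06), and ACSL1, a long-chain acyl-CoA synthetase (4.20 ± 0.38, adjusted p = 0.000395). SMPD3, a neutral sphingomyelinase, followed (3.59 ± 0.33, adjusted p = 7.56e-06). ADAMTSL3 (3.30 ± 0.29), the protocadherin PCDH9 (3.18 ± 0.19) and ZNF704 (3.16 ± 0.25) rose too. GHRH, the growth hormone-releasing hormone gene, was also called (3.42 ± 0.77, adjusted p = 0.0168), with 6.82 and 94.2 CPM in delta-like cells and a log2 fold change of 1.43 in replicate 1 alone and 5.05 in replicate 2 alone. Lower in delta-like cells was SLC30A8, the zinc transporter of insulin granules (11.2 and 1.54 against 556 and 439 CPM, log2 fold change -6.09 ± 0.87, adjusted p = 0.0334). The glutamate receptor subunit gene GRIA4 (-5.55 ± 0.41), PCDH7 (-4.73 ± 0.47), LRFN2 (-4.47 ± 0.45), EBF1 (-3.95 ± 0.60), SAMD11 (-3.49 ± 0.29) and PLPPR5 (-3.47 ± 0.25) fell. AVP, which encodes vasopressin, had 3 UMIs in delta-like and 963 in beta-like cells. Per UMI this was 145-fold more in beta-like cells (95% counting interval 49.5 to 705, adjusted p = 0.0216). By library it stood at 1.86 and 0 CPM in delta-like against 122 and 640 CPM in beta-like cells, with a log2 fold change of -5.75 in replicate 1 alone and -8.70 in replicate 2 alone.

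Among islet transcription factors, 3 of 29 tested members were higher and 6 lower in delta-like than beta-like cells (6 and 7 adjusted over the list alone). PDX1, a regulator of the insulin gene, fell (log2 fold change -1.59 ± 0.21, adjusted p = 0.000167), while RFX6 rose (1.13 ± 0.15, adjusted p = 0.000158). FGF signalling genes stood higher as a list, with 6 of 25 higher and 0 lower (7 and 0 adjusted over the list alone). Their median log2 fold change was 0.19 and their mean 0.62, so large rises in some members lifted the mean. The list includes the intracellular FGF13, and whether signalling through FGF receptors differed was not tested. Camera gave adjusted p = 0.001, and adjusted p = 0.16 with an estimated correlation. Beside FGF13, the list's lowest p-values belonged to EGR1 (1.57 ± 0.25, adjusted p = 0.00116) and DUSP6 (1.53 ± 0.31, adjusted p = 0.00811), both transcribed in response to ERK activity. Dissociation and heat shock genes also stood higher, 3 of 20 with 0 lower (6 and 0 adjusted over the list alone), among them HSPB1 (1.62 ± 0.19) and FOSB (2.64 ± 0.51). Their camera result was adjusted p = 0.00112, and adjusted p = 0.16 with an estimated correlation. Granule and prohormone processing genes stood lower, 2 higher and 8 lower of 25 (5 and 8 adjusted over the list alone), with SCG5 at -1.62 ± 0.15 and the prohormone convertase PCSK1 at -1.24 ± 0.13. The list had a camera adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation. Its call was also lost without the replicate block (adjusted p = 0.0534), with doublets kept (adjusted p = 0.0603) and with leading-hormone classes (adjusted p = 0.368), where the dissociation and heat shock call was lost too (adjusted p = 0.118).

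The other lists were not called between delta-like and beta-like cells. Of 37 ion channel genes 4 were higher and 9 lower (6 and 13 adjusted over the list alone; camera adjusted p = 0.0924), with lower KCNK17 (-1.38 ± 0.19) and CACNA1E (-2.01 ± 0.29). Receptors split 6 higher and 6 lower of 25 (9 and 7 over the list alone; adjusted p = 0.825, median log2 fold change 0.20 and mean -0.01). SSTR2, a somatostatin receptor, rose (185 and 232 against 84.0 and 73.1 CPM, 1.35 ± 0.18). FFAR1, a fatty acid receptor, had 1 UMI in delta-like and 143 in beta-like cells (64.7-fold, counting interval 11.4 to 2572; log2 fold change -5.00 without replicate 2 and -3.42 without replicate 1). Neuronal adhesion and synapse genes split 8 and 10 of 35 (10 and 12 over the list alone; adjusted p = 0.213, and adjusted p = 0.0138, called lower, with leading-hormone classes), with NLGN1 higher (2.78 ± 0.19) and LRRTM3 lower (-3.39 ± 0.32). Glucose sensing and fuel metabolism genes split 4 and 6 of 27 (4 and 6 over the list alone; adjusted p = 0.487), with ACLY lower (-1.63 ± 0.17) and TXNIP higher (3.14 ± 0.35). Exocytosis genes were 2 higher and 6 lower of 30 (3 and 7 over the list alone; adjusted p = 0.345), including CADPS (-1.29 ± 0.17) and SYT13 (-0.93 ± 0.19). Endoplasmic reticulum stress genes were 1 and 4 of 20 (3 and 7 over the list alone; adjusted p = 0.238), with lower HSP90B1 (-0.85 ± 0.14) and MANF (-0.82 ± 0.17). Gut hormone genes were 2 and 1 of 14 (3 and 1 over the list alone; adjusted p = 0.405), with SLC6A4 lower (9.30 and 9.26 against 36.9 and 37.9 CPM) and PROX1 higher (0.70 ± 0.14). Hypoxia genes were 1 and 2 of 17 (2 and 3 over the list alone; adjusted p = 0.213), with lower VEGFA (-1.58 ± 0.22) and ENO1 (-0.62 ± 0.14). Islet transcription factors as a list gave adjusted p = 0.427, with a median of 0.01 and the test's direction down.

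With classes set by the leading hormone, 382 genes were called between SST-led and INS-led cells, 283 of the 720 among them in the same direction, and SLC6A4 was no longer called (log2 fold change 0.08).

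Delta-like and alpha-like cells differed in 417 genes, 233 higher and 184 lower in delta-like cells. SV2C had the largest rise (122 and 110 against 7.67 and 3.67 CPM, log2 fold change 4.16 ± 0.28, adjusted p = 6.69e-07). GHRH (3.82 ± 0.70, adjusted p = 0.00875) and SMPD3 (3.34 ± 0.28, adjusted p = 4.33e-06) followed. Next were the extracellular matrix gene FREM1 (3.20 ± 0.60, adjusted p = 0.0454) and the cadherin-related CDHR3 (455 and 423 against 60.4 and 38.3 CPM, 3.13 ± 0.16, adjusted p = 5.81e-08). The sodium channel gene SCN3A (2.72 ± 0.18, adjusted p = 3.4e-07), the acid-sensing channel gene ASIC2 (2.72 ± 0.47) and IPCEF1 (2.71 ± 0.40) completed the 8 largest rises. PYY, the peptide YY gene of gut and early islet cells, was lower (18.6 and 12.4 against 597 and 557 CPM, -5.27 ± 0.55, adjusted p = 0.0098). The apolipoprotein gene APOA2 (-3.66 ± 0.34), PLCXD3 (-3.22 ± 0.20) and the urocortin gene UCN (-3.22 ± 0.38) were lower, as were the netrin receptor gene UNC5C (-2.84 ± 0.23), PLPPR5 (-2.84 ± 0.25), the serotonin transporter gene SLC6A4 (-2.68 ± 0.27) and LDB2 (-2.37 ± 0.16). In replicate 1 alone and replicate 2 alone, GHRH stood at 1.93 and 4.52 and UCN at -3.21 and -1.25.

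Neuronal adhesion and synapse genes were the list with the lowest p in this comparison. Of 35, 12 were higher and 2 lower in delta-like cells (12 and 2 adjusted over the list alone). Camera gave adjusted p = 3.33e-06, and adjusted p = 0.276 with an estimated correlation. UNC5D (319 and 323 against 103 and 93.4 CPM, 1.71 ± 0.13, adjusted p = 1.96e-06) and CNTNAP2 (1.65 ± 0.15, adjusted p = 6.82e-06) rose. Endoplasmic reticulum stress genes stood higher, 2 of 20 with 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.0324, and adjusted p = 0.307 with an estimated correlation). These were ERN1, a sensor of unfolded proteins (1.33 ± 0.22), and its target XBP1 (0.68 ± 0.13). Glucose sensing and fuel metabolism genes stood lower, 2 higher and 3 lower of 27 (2 and 4 adjusted over the list alone; camera adjusted p = 0.0324, and adjusted p = 0.307 with an estimated correlation). PDK3 stood at -2.17 ± 0.19. With the stricter cell filter the calls of the endoplasmic reticulum stress (adjusted p = 0.634) and glucose sensing (adjusted p = 0.209) lists were lost, the latter also with leading-hormone classes (adjusted p = 0.597).

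Islet transcription factors split 4 higher and 4 lower of 29 (7 and 4 over the list alone; adjusted p = 0.311). PAX6 (68.8 and 47.9 against 241 and 305 CPM, -2.17 ± 0.22) was lower and FOXA2 (0.88 ± 0.14) higher. Granule and prohormone processing genes were 4 higher and 5 lower of 25 (4 and 8 over the list alone; adjusted p = 0.136). PCSK1, lower against beta-like cells, was higher against alpha-like cells (515 and 292 against 182 and 111 CPM, 1.45 ± 0.13). PAM rose (1.29 ± 0.13) and SCG5 fell (-1.57 ± 0.15). FGF signalling genes were 5 higher and 1 lower of 25 (5 and 1 over the list alone; adjusted p = 0.136), with FGF13 (1.43 ± 0.16) and DUSP6 (2.01 ± 0.30) higher. Receptors were 4 and 3 of 25 (9 and 6 over the list alone; adjusted p = 0.509), with SSTR2 lower (-1.01 ± 0.16) and FFAR1 at 1 UMI against 247 (51.8-fold, counting interval 9.21 to 2055). Ion channel genes were 5 and 3 of 37 (5 and 5 over the list alone; adjusted p = 0.601), with KCNJ6 lower (-0.97 ± 0.14) beside the higher SCN3A. Gut hormone genes were 2 and 2 of 14 (3 and 6 over the list alone; adjusted p = 0.15), and RGS2 was higher (2.06 ± 0.28). Exocytosis genes were 0 and 3 of 30 (4 and 4 over the list alone; adjusted p = 0.552), with SYT7 (-0.60 ± 0.15) lower. Dissociation and heat shock genes were 2 and 0 of 20 (2 and 0 over the list alone; adjusted p = 0.136), with HSPB1 (0.82 ± 0.18) and IER3 (1.02 ± 0.23) higher. Hypoxia genes were 0 and 2 of 17 (0 and 2 over the list alone; adjusted p = 0.509), with VEGFA (-0.80 ± 0.22) and BNIP3 (-0.53 ± 0.15) lower. Of these lists, granule genes were called lower with the stricter cell filter (adjusted p = 0.00154) and gut hormone genes lower with doublets kept (adjusted p = 0.00521). With leading-hormone classes FGF signalling (adjusted p = 0.038) and ion channel genes (adjusted p = 0.00586) were called higher. In replicate 1 alone and replicate 2 alone, HSPB1 stood at 1.05 and 0.40 and VEGFA at -1.12 and -0.29.

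With classes set by the leading hormone, SST-led and GCG-led cells differed in 55 genes, 42 of the 417 among them. SV2C, SMPD3, SCN3A, UNC5D and CNTNAP2 kept their call and direction, CDHR3 missed the threshold, and PYY was no longer called (log2 fold change 0.71). At Leiden resolution 2, HSPB1 (-0.07) and BNIP3 (0.25) lay on the other side of 0 without a call.

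**Figure D4:**
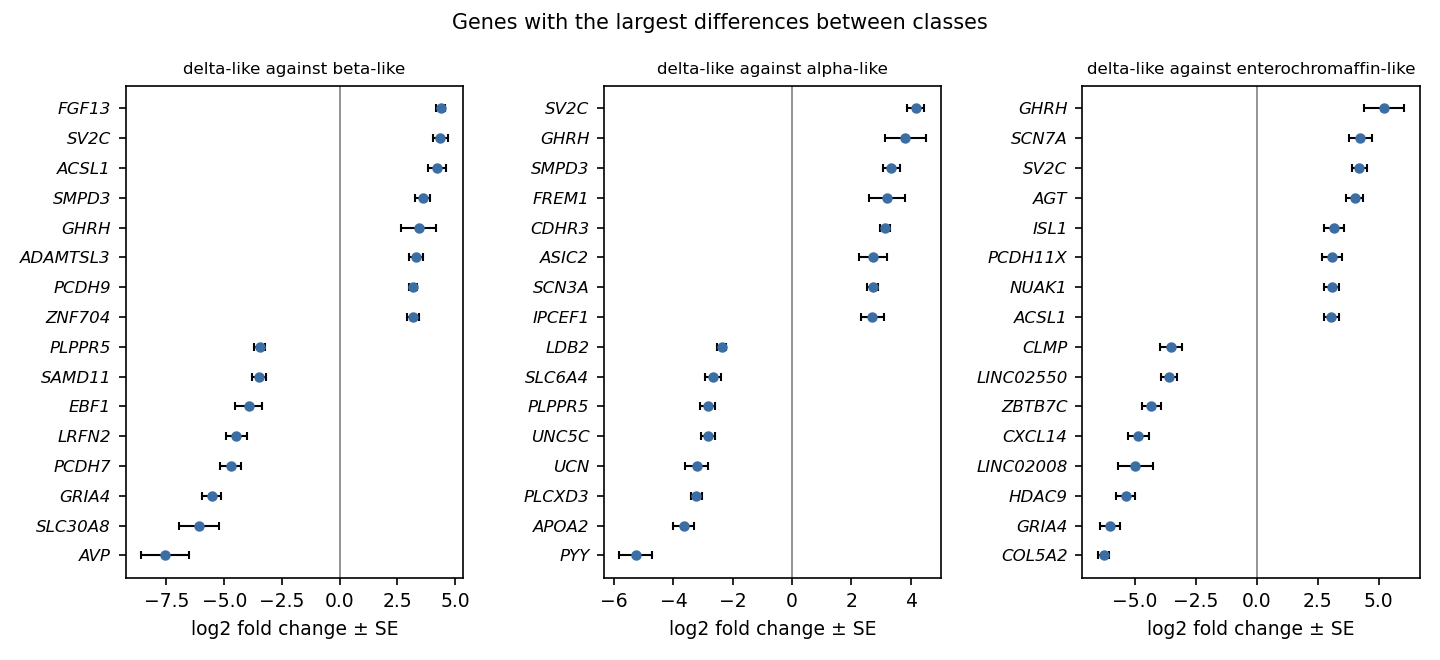
Log2 fold change ± SE (edgeR, 2 libraries) of the 8 genes with the largest rise and the 8 with the largest fall in delta-like cells, in each comparison; points right of 0 are higher in delta-like cells. SV2C is among the 8 largest rises in each panel, at 4.35, 4.16 and 4.21.

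Against enterochromaffin-like cells, 867 genes differed, 438 higher and 429 lower in delta-like cells. The largest rises were in GHRH (5.23 ± 0.83, adjusted p = 0.00177) and the sodium channel gene SCN7A (39.7 and 63.3 against 2.42 and 2.62 CPM, 4.25 ± 0.48, adjusted p = 0.00024). SV2C (4.21 ± 0.30, adjusted p = 8.56e-07) rose again, as did AGT, the angiotensinogen gene (4.02 ± 0.34), and ISL1, an islet transcription factor (249 and 205 against 34.7 and 12.1 CPM, 3.16 ± 0.42, adjusted p = 0.00898). PCDH11X (3.09 ± 0.40), the kinase gene NUAK1 (3.07 ± 0.31) and ACSL1 (3.05 ± 0.32) completed the 8. The largest fall was in the collagen gene COL5A2 (5.58 and 4.63 against 527 and 212 CPM, -6.30 ± 0.25, adjusted p = 1.82e-09). GRIA4 (-6.04 ± 0.41) and the histone deacetylase gene HDAC9 (-5.39 ± 0.41) followed, then the non-coding RNA genes LINC02008 (-5.00 ± 0.73) and LINC02550 (-3.60 ± 0.32), the chemokine gene CXCL14 (-4.87 ± 0.42), ZBTB7C (-4.34 ± 0.39) and CLMP (-3.52 ± 0.44). GHRH stood at 3.11 in replicate 1 alone and 4.94 in replicate 2 alone.

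Endoplasmic reticulum stress genes stood higher in delta-like than enterochromaffin-like cells, with 10 of 20 higher and 0 lower (13 and 0 adjusted over the list alone). Camera gave adjusted p = 1.62e-06, and adjusted p = 0.125 with an estimated correlation. XBP1 (317 and 330 against 139 and 139 CPM, 1.21 ± 0.14, adjusted p = 3.62e-05) and ERN1 (1.80 ± 0.23) had the lowest p. Dissociation and heat shock genes followed, 5 of 20 with 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.000488, and adjusted p = 0.142 with an estimated correlation). HSPB1 (1.59 ± 0.18) and IER3 (1.29 ± 0.23) rose. FGF signalling genes were 7 higher and 1 lower of 25 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0321, and adjusted p = 0.169 with an estimated correlation). FGF13 (2.33 ± 0.16) and DUSP6 (1.83 ± 0.30) rose. Granule and prohormone processing genes were 11 higher and 5 lower of 25 (11 and 7 adjusted over the list alone; camera direction up, adjusted p = 0.0149, and adjusted p = 0.156 with an estimated correlation). Their median was -0.02 and their mean 0.24. SEC11C (2.47 ± 0.16) and TTR (1.77 ± 0.19) rose, and CHGA, the chromogranin A gene, fell (4294 and 4339 against 16380 and 16980 CPM, -1.95 ± 0.21). Exocytosis genes stood lower, 2 higher and 8 lower of 30 (2 and 10 adjusted over the list alone; camera adjusted p = 0.00319, and adjusted p = 0.156 with an estimated correlation). SYT13 stood at -2.33 ± 0.18 and RAB3C at -1.56 ± 0.18. The FGF signalling call was lost without the replicate block (adjusted p = 0.103), under count splitting (adjusted p = 0.0837), with the stricter cell filter (adjusted p = 0.168) and with doublets kept (adjusted p = 0.488), where the list's median was 0.10 against the reported fit's 0.41. The granule call was lost under count splitting (adjusted p = 0.515) and with the stricter filter (adjusted p = 0.137). The exocytosis call was lost with the stricter filter (adjusted p = 0.0915) and with doublets kept (adjusted p = 0.269).

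The other lists were not called. Glucose sensing and fuel metabolism genes were 5 higher and 1 lower of 27 (5 and 1 over the list alone, adjusted p = 0.375), with TXNIP (2.03 ± 0.29) and PDK3 (1.41 ± 0.23) higher. Neuronal adhesion and synapse genes were 10 and 7 of 35 (12 and 8 over the list alone, adjusted p = 0.375, test direction up with a median of -0.08), with CNTNAP2 higher (2.64 ± 0.15) and NLGN1 lower (-1.14 ± 0.16). Under count splitting this list was called higher, with 9 higher and 2 lower (adjusted p = 0.00086, median 0.48). Ion channel genes were 4 and 5 of 37 (5 and 8 over the list alone, adjusted p = 0.405), with ITPR3 lower (-2.51 ± 0.21) and KCNK16 higher (1.80 ± 0.19). Islet transcription factors were 2 and 4 of 29 (4 and 5 over the list alone, adjusted p = 0.405, median -0.03 and mean 0.01), with MNX1 (-1.69 ± 0.15) and NKX2-2 (-1.48 ± 0.19) lower. Receptors were 4 and 5 of 25 (4 and 6 over the list alone, adjusted p = 0.273), with SSTR1 lower (-2.66 ± 0.38) and GRIA3 higher (1.24 ± 0.18). Gut hormone genes were 1 and 2 of 14 (1 and 2 over the list alone, adjusted p = 0.804, median 0.18 and mean -0.20), with PROX1 higher (0.75 ± 0.14) and TRPA1 at 1 UMI against 88 (29.1-fold lower, counting interval 5.09 to 1163). Hypoxia genes were 1 and 1 of 17 (0 and 0 over the list alone, adjusted p = 0.375), with GBE1 (0.48 ± 0.14) and BNIP3 (-0.48 ± 0.15) called. In replicate 1 alone and replicate 2 alone, log2 fold changes were 2.44 and 1.16 for TXNIP, 1.74 and 0.80 for PDK3, 1.59 and 0.77 for GRIA3, -0.65 and -0.26 for BNIP3 and -3.95 and -2.25 for TRPA1; at Leiden resolution 2 BNIP3 stood at 0.01 without a call.

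The treatment is labelled "FGF2+7", and the receptors of the FGF family were compared in every class. FGFR1 (chromosome 8, 38400215 to 38468834) was the most abundant of them in delta-like cells, at 96.7 and 122 CPM. Its log2 fold change was 0.19 ± 0.15 against beta-like cells (adjusted p = 0.542), -0.15 ± 0.14 against alpha-like cells (adjusted p = 0.664) and 0.82 ± 0.15 against enterochromaffin-like cells (adjusted p = 0.00193). In replicate 1 alone and replicate 2 alone, FGFR1 stood at 0.12 and 0.26 against beta-like and at -0.24 and -0.03 against alpha-like cells. FGFR2 (chromosome 10, 121478334 to 121598458) was low in delta-like cells, at 12.4 and 7.72 CPM, and lower than in alpha-like cells (-1.11 ± 0.31, adjusted p = 0.0469) and enterochromaffin-like cells (-1.38 ± 0.31, adjusted p = 0.00729). Against beta-like cells it was -0.05 ± 0.36 (adjusted p = 0.975), at -0.07 in replicate 1 alone and 0.16 in replicate 2 alone. Cells outside the endocrine clusters held FGFR2 at 157 and 136 CPM. FGFR3 (10.5 and 3.09 CPM in delta-like cells) and FGFR4 (31.0 and 17.0 CPM) were called in no comparison. Adjusted p (edgeR) ranged from 0.169 to 0.999 for FGFR3 and from 0.668 to 0.817 for FGFR4. In replicate 1 alone and replicate 2 alone, FGFR3 stood at 0.38 and -1.83 against beta-like, 0.57 and -1.44 against alpha-like and -0.75 and -1.94 against enterochromaffin-like cells. FGFR4 stood at 0.60 and -0.82, 0.62 and -0.47, and 0.43 and -0.53 in the same order.

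Most cells lay outside the endocrine clusters. Duct or pancreatic progenitor-like cells made up 0.203% of replicate 1 and 9.70% of replicate 2, gastric-like cells 0.677% and 5.35%, mesenchymal-like cells 0.449% and 0.308%, and neural crest or glial-like cells 1.86% of replicate 2 and 0 of 15802 cells of replicate 1 (95% upper limit 0.0233%). The unnamed clusters included cells led by KRT1, KRT15 and SPRR1B (11.1% and 0.127%), by RSPO3 and ZIC1 (12.8% and 0.244%), and by PAX1 and PAX9 (0.044% and 14%). Others were led by SFRP2 and EDNRB (0.797% and 15.6%), by STMN2 and DCX (2.46% and 8.05%), and by GIF and ATP4B, genes of gastric parietal cells (2.37% and 2.36%). Of 28 clusters outside the endocrine ones, 18 drew at least 90% of their cells from 1 library after scaling to library size, of which 8 were of replicate 1 and held 62.7% of its cells and 10 were of replicate 2 and held 67.4% of its cells.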

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

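The tests of free RNA were chosen only after the result was seen; the other tests were set out before theirs. No biological explanation was tested for any pattern below, since all libraries belong to 1 group and no label says whether the cultures were separate.

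SST led the hormones in cells outside the endocrine clusters, in groups of cells that no comparison between classes used. Clusters were flagged where such cells numbered above the limit that a count of 0 allows. The limit uses no background share, so a flag alone does not show that a cluster is enriched in SST-led cells. In replicate 2 they included 28 of 758 cells (3.69%, 95% interval 2.47 to 5.30) of cluster 3, led by STMN2, DCX and SLC6A5 (3 of 389 in replicate 1, 0.771%), and 27 of 209 cells (12.9%, 8.69 to 18.2) of cluster 22, led by SYN3 and PLXNA4. Free RNA of the endocrine cells was argued against: the 56 SST-positive cells would need 48.5% of the pooled endocrine excess to reach their SST level, and the median over the 20 other transcripts with the largest excess, INS left out, was -2.83%, or -0.058 of the need. Doublets with delta-like cells were argued against too: these cells would need 9.62% of the delta-like excess, and the median over its 20 largest transcripts was -0.67%, or -0.07 of the need. Both tests pooled the clusters and did not match SST-positive to SST-negative cells by cluster. SST-led cells were 27 of 209 in cluster 22 against 28 of 758 in cluster 3, so differences between the clusters could enter both medians. Transcription of SST in these cells may account for the UMIs, as a hypothesis found and tested on the same data in 1 library.

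SST was abundant in alpha-like cells, with at least 10 UMIs in 47.4% of them in replicate 1 and 41.0% in replicate 2 (61.0% and 64.3% of beta-like cells), at 12397 and 9014 CPM (2736 and 813 CPM in beta-like cells). SST per INS UMI in alpha-like cells was 3.36 and 3.81, against 0.502 and 0.619 in cells outside the endocrine clusters, and the lower of the libraries' ratios was 6.16, which argues against free RNA as the whole source. Doublets with delta-like cells would need 47.7% and 79.8% of the delta-like excess, whereas the median over genes higher in delta-like than alpha-like cells was -1.71% and 1.31%, at most 0.016 of the need. These genes came from a comparison in which the tested cells were part of the alpha-like class, so genes raised in them were less likely to be chosen. Cells with much delta-like RNA could also have been clustered elsewhere or removed as doublets. The medians thus describe the cells kept in the alpha-like class and cannot exclude doublets. Co-expression of SST and GCG in cells of an alpha-like state may account for the values, as a hypothesis.

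The libraries differed in make-up, with 18 of 28 clusters outside the endocrine ones at least 90% from 1 library. If the cell filter or depth made the difference, summing all deposited barcodes would give like marker levels. Instead, 12 fixed duct and neural crest markers differed by a median of 1.49 on the log2 scale (95% lower bound 1.17). Their difference was thus present before the filter used here. The test cannot decide more, since most deposited barcodes were kept (15802 of 19158 and 9421 of 10296). The markers also came from classes already seen almost wholly in replicate 2. None stood for the 8 clusters drawn at least 90% from replicate 1. Of the 12 markers, 10 were higher in replicate 2. The duct markers KRT19 and KRT7 were higher in replicate 1 (log2 ratio of replicate 2 over replicate 1 -1.45 and -1.13). For the other clusters the cell filter and depth stay open. Differences between cultures or runs stay open for all clusters, since no label gives any of them.

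SST-led cells were also above the limit that a count of 0 allows in other clusters outside the endocrine ones, with no explanation tested. Cluster 0, led by REG1A with INS among its 10 leading genes, held SST-led cells as 59 of 2350 (2.511%, 95% interval 1.92 to 3.23) in replicate 1 and 8 of 67 (11.94%, 5.30 to 22.2) in replicate 2; the median depth of the cluster was 1064 UMIs. In replicate 1, clusters 9, 11, 16 and 18 held 4 such cells each (1.347%, 0.197%, 0.282% and 0.659%). These shares were not compared with that of all cells outside the endocrine clusters, so enrichment is not shown.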

How the results depend on the processing

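Classes by leading hormone and the settings with at least 10 cells were chosen only after the results were seen. Without either library, the delta-like share ranged from 0.414% to 1.11% and the SST-led share from 1.36% to 2.55%. The delta-like share was 0% at Leiden resolution 0.5 and with library-centred genes, where no sub-cluster earned the name. It was 0.370% with all variable genes and 0.287% at Leiden resolution 2, and 0.595% and 0.244% in replicates 1 and 2 under count splitting. The SST-led share was 3.59% at 5 UMIs; the cause was not tested. Of called and uncalled named genes over all alternatives, 2026 values were counted as the same, 395 lost and 14 gained a call, 16 reversed and 6 moved. The 2026 include 193 values without replicate 1 and 195 without replicate 2, judged on direction alone since no test was possible. In tested settings, an uncalled gene that changed sign and stayed uncalled was also counted as the same. Of gene list values 184 were the same, 26 lost and 6 gained a call, and 0 of 36 lists were called with an estimated correlation.

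Counts of genes outside 1.5 times the reported 720, 417 and 867 were as follows. Without the replicate block they were 393 against beta-like, 166 against alpha-like and 532 against enterochromaffin-like cells. Count splitting, which leaves fewer UMIs, gave 357 against beta-like and 509 against enterochromaffin-like cells. The stricter cell filter, which leaves fewer cells, gave 362, 213 and 412, the first at a minimum of 10 cells. Leiden resolution 2 at 10 cells gave 259, 148 and 511. Classes by leading hormone gave 382 against beta-like and 55 against alpha-like cells. Against alpha-like cells, no low-count filter gave 718 among 13323 tested genes and the fit of only 2 classes 652. Whether cell and UMI numbers account for these counts was not tested, nor was any other cause. The SST-led class held 254 and 52 cells, more than the 176 and 39 delta-like cells. At a minimum of 10 UMIs, SST-led cells were found in the alpha-like class (147 and 26) as well as in the delta-like class (116 and 27).

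Reversed log2 fold changes, all without a call, were 0.077 for SLC6A4 against beta-like cells with leading-hormone classes. Against alpha-like cells they were TXNIP -0.068, CASR 0.16, KCNK17 0.085, KCNK16 0.22, HSPB1 -0.068 and BNIP3 0.25 at Leiden resolution 2. With all variable genes they were CASR 0.30, KCNK17 0.12, KCNK16 0.52 and BNIP3 0.043, with count splitting CASR 0.25, and with leading-hormone classes CASR 0.57, MLXIPL 0.014 and PYY 0.71. Against enterochromaffin-like cells BNIP3 was 0.010 at Leiden resolution 2. The cause was not tested.

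Leiden resolution 0.5 and library-centred genes gave no gene counts, having no delta-like class. At the minimum of 20 cells, Leiden resolution 2 had 16 delta-like cells in replicate 2, the stricter filter 14 beta-like, count splitting 14 alpha-like, and all variable genes 19 delta-like and 15 alpha-like cells. Leading-hormone classes held no enterochromaffin-like cells. With 1 library left there are no residual degrees of freedom, so leaving a library out gave values and no tests. The 39 delta-like cells of replicate 2 held 636664 UMIs, the smallest sum of any class, which limits genes of low abundance.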

Other observations

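The values in this part were chosen only after the data were seen, and none was tested. Cells with at least 10 SST UMIs differed in other RNA between the delta-like and alpha-like classes. In the delta-like class (121 and 30 cells in replicates 1 and 2) they held HHEX at 50.8 and 62.4 CPM, GHRL at 858 and 3944 CPM, GCG at 533 and 2.08 CPM and PYY at 20.5 and 16.7 CPM. In the alpha-like class (357 and 41 cells) they held HHEX at 1.15 and 12.3 CPM, GHRL at 7.35 and 14.8 CPM, GCG at 28107 and 7514 CPM and PYY at 889 and 612 CPM, with SST itself at 24205 and 22028 CPM. SV2C and CDHR3 stood at 144 and 131 CPM and 433 and 360 CPM in the first class, against 8.27 and 2.47 CPM and 37.2 and 44.4 CPM in the second.

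Gastrin RNA was present in the alpha-like class. GAST stood at 595 and 2232 CPM in alpha-like cells with fewer than 10 SST UMIs and at 254 and 721 CPM in those with more, while PYY stood at 244 and 480 CPM in the former. Among delta-like cells, the 55 and 9 with fewer than 10 SST UMIs held HHEX at 0 CPM in both libraries, GCG at 3238 and 218 CPM, GHRL at 258 and 5723 CPM and CDHR3 at 563 and 647 CPM. An epsilon-like class, named for GHRL, was set apart with 20 and 10 cells at Leiden resolution 2, 19 and 10 with library-centred genes and 21 and 9 with all variable genes. SST-positive cells of clusters 3 and 22 in replicate 2 (56 cells) held SST at 2712 CPM with STMN2 at 2863 CPM and SV2C at 133 CPM, and TTR, abundant in delta-like cells, at 53.9 CPM.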
